A study of Rattus norvegicus with 3 samples.

How the data were processed

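Renal proximal tubules of male Sprague-Dawley rats aged 7 to 8 weeks were profiled on 3 Affymetrix rat expression arrays, 1 per tubule preparation. Per the labels, the animals received 250 units of heparin into the peritoneum 30 min before decapitation. The kidneys were perfused backwards through the aorta with 10 ml of cold phosphate-buffered saline and 10 ml of collagenase at 2 mg/ml. The cortex was then digested for 20 min, and the tubules were collected on a 42.5% Percoll density gradient. Total RNA was extracted with Trizol and biotin-labelled cRNA was made by the array maker's protocol. The labels do not say whether a preparation came from 1 animal or from several, nor whether the 3 preparations came from different animals.

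The deposited values were probe-set signal intensities on a linear scale, with 31099 probe sets per array, of which 57 were control probe sets. The sources used here give neither the summarisation software nor the scaling between arrays, and the array medians differed slightly, so the values were taken as deposited. No detection p-values were used here, so no probe set was called present or absent. The number of arrays limits the precision of every value.

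Gene symbols came from the probe annotation provided with the values. Of the probe sets, 20826 named 1 gene, 436 named several genes and were left out, and 9780 had no gene named here. Of the 1-gene probe sets, 20758 were matched by gene identifier to a RefSeq gene table of the GRCr8 assembly, which changed 0 symbols and from which no coordinates were used. Each of the 14217 named genes took its value from its probe set of highest mean signal; 4525 genes had more than 1 probe set. Control probe sets were left out of gene values and of array medians.

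All 3 arrays formed 1 group with no control group, so no difference between conditions was tested. The level of a gene list was the median percentile of its members among all named genes on an array, averaged over the 3 arrays. It was compared with 10000 random gene lists of the same size (two-sided gene-permutation p, smallest possible value 0.0002). The 50 lists, of which 34 were lists of named genes and 16 were families defined by a symbol pattern, were adjusted together by the Benjamini-Hochberg method at 0.05. The 34 lists held 14 of cell type markers, 17 of proximal tubule functions and 3 of handling and injury responses. Genes are not independent replicates, so these p-values describe genes on these arrays and not a population of animals. The proximal tubule list was also compared directly with each of the 13 other cell type lists by a two-sided permutation test with 100000 resamples of list membership, for which the smallest possible p is 1e-05. Members above the median signal of all non-control probe sets on all 3 arrays were counted and compared with all other named genes by a two-sided Fisher's exact test. Probe sets differ in affinity, so levels of different genes were not ranked against each other, and percentiles were read for lists only.

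For comparisons between arrays, values were transformed as log2(signal + 16) and centred on the median of each array. Genes above the median level were counted when their range over the arrays reached 1 log2 unit (2-fold). The shift of a list on an array was the median deviation of its members from their own means over the 3 arrays. It was placed among 10000 random lists matched on the decile of mean level and called outside chance when it lay outside their central 95%, without a p-value, since each array was a single sample. Intervals in the closing section are 95% bootstrap intervals over genes from 10000 resamples.

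Gene lists, tests and alternatives of the report and the rule for naming genes were fixed before the data were examined. The lists of interferon, clock and glucocorticoid response genes and of further cell markers, and the tests of the closing section, were added for patterns seen in the data. The rule allowed the 4 highest members and the lowest member of each proximal tubule, function and handling list to be named. It also allowed the 2 highest members and the lowest member of each other cell type list. The 2 highest of each family and 21 preset kidney genes were allowed as well. Further allowed were the 15 genes of highest mean signal and the 10 genes of largest range between arrays above the median level. For each list shift outside chance, its 2 members of largest deviation were allowed too. Not all genes that the rule allowed are named below. The rule chose names and did not rank genes. Genes named outside this rule are identified as chosen after their values were seen. Alternatives were the mean of a gene's probe sets, only probe sets without a suffix for shared transcripts, random lists matched on the number of probe sets, and removal of the lowest 20% of genes. Others were lines at the 25th and 75th percentiles, pseudocounts of 1 and 64, quantile normalization, no centring, other filters on low values, the mean as the statistic and leaving out each array in turn.

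The procedures were tested on simulated lists on the 14217 genes. Of 100 lists of 15 genes drawn at random, 1% were called by the level test. Of 100 lists of 15 genes planted at a median percentile near 78.9, 27% were called, and of 100 planted near 63.8, 1% were called, so a list that was not called was not shown to lie at the level of all genes. In the shift test on lists of 10 genes, 3% of 100 lists were called with no planted shift. With log2 0.2 planted, 55% of 20 lists were called, and with log2 0.4, 85% of 20. In the measure used here, the median deviation of a list, these planted lists shifted by a mean of only 0.13 and 0.24. Rates from simulated lists may not hold for real lists, whose genes can vary together. The rates of the level test also depend on how many lists are adjusted together. In the comparison of the proximal tubule list with other lists, 6% of 100 lists of 12 genes were called without a planted difference and 71% with one near 28.0 percentile points. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.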

Results

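The labels state the aim as describing the transcripts present in the rat renal proximal tubule, the nephron segment that reclaims most of the filtered sodium, glucose, amino acids, phosphate and bicarbonate. Tubules from 3 preparations were each measured on 1 array, giving signals for 31099 probe sets and 14217 named genes. The median signal was 37.1 on array 1, 37.4 on array 2 and 34.9 on array 3, and the maximum was 15826, 14313 and 15213. The 75th percentile was 181, 167 and 167. Signals of genes are given as mean ± SD over the 3 arrays (n = 3) throughout, and levels of different genes are not ranked because probe sets differ in affinity.

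The first comparison set markers of proximal tubule cells beside markers of other kidney, blood and non-kidney cells. Proximal tubule markers had a median percentile of 99.1 among all named genes, with 25 of 27 listed genes measured, and all 25 lay above the array median on all 3 arrays. They included Lrp2 (8550 ± 570) and Cubn (4926 ± 327), the receptors of protein reabsorption, Slc34a1 (9616 ± 380), the main sodium-phosphate cotransporter, and Slc5a2 (3443 ± 319), the glucose cotransporter of the early segment. Gatm, the first enzyme of creatine synthesis, gave 10604 ± 137. Miox, which breaks down inositol, gave 9935 ± 602, and Pck1, the key enzyme of gluconeogenesis, gave 9415 ± 413. Dpep1, a brush border dipeptidase, gave 112 ± 25.8. Non-kidney tissue markers (median percentile 15.1) and lymphocyte markers (15.8) lay below random lists. Among them, Gh1 of the pituitary gave 27.4 ± 6.06, Ins1 of the pancreas 52.0 ± 4.40, Snap25 of neurons 1.64 ± 0.430, Ptprc of white blood cells 22.04 ± 4.75, Lck of T cells 32.3 ± 5.59 and Cd3d 2.69 ± 1.24.

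The proximal tubule list lay above random lists (adjusted permutation p = 0.00045), and the non-kidney (adjusted permutation p = 0.00045) and lymphocyte lists (adjusted permutation p = 0.0016) lay below. The other 11 cell type lists were not called. Set directly against each of the 13 other lists, the proximal tubule list was higher by 39.7 to 84.1 percentile points on the mean of 3 arrays, with adjusted permutation p-values from 2.6e-05 to 0.00063. The smallest difference was to the thick ascending limb list and the largest to the non-kidney list. In the count of members above the array median, 0 of 12 lymphocyte genes, 1 of 23 non-kidney genes and 1 of 9 podocyte genes passed on all 3 arrays (Fisher's exact test, adjusted p = 5.6e-05, 1.2e-07 and 0.0071).

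**Figure D1:**
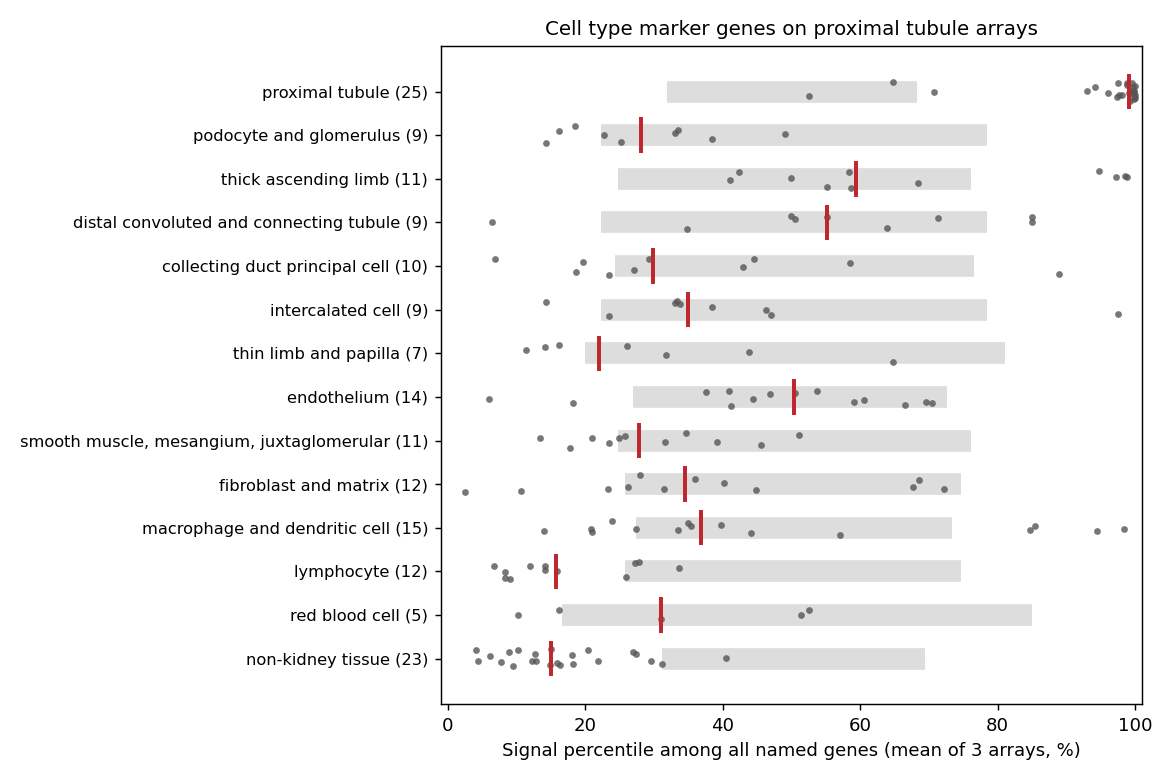
Signal percentile of each marker gene among all named genes (x axis, %, mean of 3 arrays) for 14 cell type lists (y axis, number of measured genes in parentheses). Each point is a gene, the red bar is the list median and the grey band holds 95% of random lists of the same size; the proximal tubule median of 99.1 lies right of its band, and the lymphocyte (15.8) and non-kidney (15.1) medians lie left of theirs.

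Within the lists of other nephron segments, some genes lay far above the array median. In the thick ascending limb list (median percentile 59.4), Umod, the gene of uromodulin, gave 4942 ± 656, Egf gave 4340 ± 331 and Slc12a1, the sodium-potassium-chloride cotransporter, gave 1810 ± 258, while Cldn19 gave 58.6 ± 28.9. In the distal convoluted and connecting tubule list (55.1), Slc12a3, the thiazide-sensitive cotransporter, gave 660 ± 119, Slc16a7 gave 649 ± 30.1 and Pvalb gave 2.52 ± 1.09. The collecting duct principal cell list (29.9) held Aqp3 at 868 ± 66.6 and Hsd11b2 at 154 ± 35.99, but the vasopressin-regulated water channel Aqp2 gave 13.999 ± 16.4 and Aqp4 gave 4.01 ± 5.36. The intercalated cell list (34.9) held Atp6v0a4, a proton pump subunit, at 3231 ± 115, against Atp6v1g3 at 80.9 ± 22.6 and Kit at 8.34 ± 8.41. The thin limb list (21.98) held Akr1b1 at 206 ± 5.78, Slc4a11 at 65.4 ± 7.09 and Aldh1a3 at 5.47 ± 3.57.

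Outside the tubule epithelium, the endothelial list (median percentile 50.3) held Plvap at 289 ± 106 and Kdr at 269 ± 62.3, with Pecam1 at 84.8 ± 48.2 and Sele at 3.12 ± 3.93. The fibroblast list (34.5) held Pdgfra at 302 ± 26.4, Fn1 at 250 ± 12.8 and Lum at 1.23 ± 0.735. In the macrophage and dendritic cell list (36.8), Cd74, the invariant chain of MHC class II, gave 4263 ± 1086 and RT1-Da, a class II chain, gave 1879 ± 707, while Cd163 gave 7.14 ± 2.60. The podocyte list (28.2) held Podxl at 91.1 ± 25.9, Synpo at 48.1 ± 18.8 and Clic5 at 10.3 ± 13.96. The smooth muscle list (27.8) held Smtn at 102 ± 11.1, Acta2 at 72.8 ± 3.39 and Cnn1 at 7.71 ± 5.35. The red blood cell list (31.0) held Slc25a37 at 112 ± 26.5, the globin gene Hbb at 110 ± 54.5 and Ahsp at 6.34 ± 8.24. Of the 124 genes in these 12 lists of other kidney and blood cells, 20 also stood in a list of functions or a family, and 54 lay above the array median on all 3 arrays.

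The next comparison asked which functions and segments of the proximal tubule stood above the level of all genes. The 4 transport lists and the lists of endocytosis, of the brush border and of the early segment lay above random lists, and the late segment list was not called. Early segment genes had a median percentile of 99.3, basolateral transporters 98.9, endocytosis and lysosome genes 98.2, brush border genes 94.1, water, bicarbonate and tight junction genes 92.4, apical sodium-coupled and proton-coupled uptake genes 92.1 and organic ion and drug transporters 87.8. The adjusted permutation p was 0.00087 for organic ion transport and 0.00045 for each of the other 6, and the lowest median percentile of the 7 lists on a single array was 85.8, for organic ion transport on array 3. Late segment genes had a median percentile of 57.8 (adjusted permutation p = 0.63). The early list shares Slc5a2, Slc5a12, Slc6a19, Slc4a4, Slc34a1, Gatm and Pck1 with the proximal tubule list, and the late list only Slc7a13. The level of the early list therefore largely repeats that of the proximal tubule list.

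In the basolateral list, Atp1b1, a subunit of the sodium pump, gave 9127 ± 744, Slc4a4, the sodium-bicarbonate cotransporter, gave 7331 ± 502, Slc13a3, a dicarboxylate carrier, gave 7101 ± 735 and the potassium channel gene Kcnj15 gave 6609 ± 274. Slc2a2, the basolateral glucose carrier, gave 2667 ± 264. In the apical list, Slc3a1 (8801 ± 781) and Slc7a9 (4610 ± 321), which form the cystine transporter, stood beside Slc34a1, and all 17 measured members lay above the array median on all 3 arrays. Slc9a3, the sodium-proton exchanger, gave 1199 ± 180, and Slc5a1, the glucose cotransporter of the late segment, gave 39.6 ± 4.25. In the organic ion list, the anion carriers Slc22a8 and Slc22a6 gave 6412 ± 369 and 4779 ± 644, the drug exporter Slc47a1 gave 4047 ± 572, the carnitine carrier Slc22a5 gave 3068 ± 459 and Slc22a13 gave 7.82 ± 5.79. In the late segment list, Acsm3 gave 3282 ± 568, Slc1a1 2192 ± 383, Gclm 947 ± 115 and Serpina1 11.7 ± 8.43.

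The endocytosis and lysosome list held the cathepsin genes Ctsl (10622 ± 1103), Ctsh (9434 ± 696) and Ctsb (8442 ± 393) and Clcn5, a chloride-proton exchanger of endosomes, at 34.2 ± 4.13. The brush border list held the scaffold gene Pdzk1 (5356 ± 119), the peptidase genes Dpp4 (4300 ± 513) and Anpep (3831 ± 691), and Ezr (3749 ± 216), while Treh, the trehalase gene, gave 1.34 ± 0.350. In the water and bicarbonate list, the water channel gene Aqp1 gave 3796 ± 155, the carbonic anhydrase gene Car2 gave 3833 ± 399, the proton pump gene Atp6v1a gave 3390 ± 392 and Cldn1 gave 114 ± 11.04. Members above the array median on all 3 arrays numbered 18 of 19 for endocytosis (Fisher's exact test, adjusted p = 0.0037), 16 of 16 for water and bicarbonate (0.0011) and 13 of 14 for basolateral transport (0.024), but 17 of 21 for the brush border (0.11) and 14 of 19 for organic ions (0.42).

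Metabolic pathways were compared with all genes in the same way. TCA cycle genes (median percentile 98.1), amino acid catabolism genes (97.3), xenobiotic and glutathione genes (94.5), gluconeogenesis and fructose genes (93.9) and fatty acid oxidation and peroxisome genes (93.6) all lay above random lists, each with an adjusted permutation p of 0.00045. Members above the array median on all 3 arrays were 16 of 16 for the TCA cycle (Fisher's exact test, adjusted p = 0.0011) and 32 of 33 for amino acid catabolism (1.5e-05). They were 29 of 32 for xenobiotic metabolism (0.0010) and 25 of 26 for fatty acid oxidation (0.00021). For gluconeogenesis they were 10 of 11, which did not pass (0.096). Glycolysis genes had a median percentile of 69.1 and were not called (adjusted permutation p = 0.12). Liver-restricted urea and plasma protein genes had a median percentile of 26.1 (adjusted permutation p = 0.057), and 1 of 15 lay above the array median on all 3 arrays (Fisher's exact test, adjusted p = 6.8e-05). The liver list passed the level test with only probe sets without a shared-transcript suffix (adjusted permutation p = 0.038), without the lowest 20% of genes (0.0076) and without array 1 (0.042).

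In amino acid catabolism, Hao2, a hydroxyacid oxidase of peroxisomes, gave 10907 ± 820, Ass1, which makes argininosuccinate, gave 10090 ± 454 and Hpd of tyrosine breakdown gave 9614 ± 649. In gluconeogenesis, Fbp1 gave 8535 ± 458, Sord of the polyol pathway 6566 ± 477, the glucose 6-phosphate carrier Slc37a4 4750 ± 370 and Fbp2, a muscle form, 42.8 ± 15.3. In the TCA cycle, Idh2 gave 6942 ± 136, Sdha 5657 ± 479, Sdhc 5421 ± 505, Suclg2 4652 ± 630 and Idh3a 1391 ± 202. In fatty acid oxidation, the catalase gene Cat gave 7420 ± 351, Slc27a2 5895 ± 325, Acadm 4952 ± 301, Acaa2 4743 ± 624 and Acox2 21.1 ± 7.63. In the xenobiotic list, Gpx3, the secreted glutathione peroxidase, gave 12680 ± 794, the aldehyde reductase gene Akr1a1 10430 ± 520, Cyp2c23 9284 ± 873, Gsta1 7218 ± 1019 and Ugt2b1 10.8 ± 8.45. The glycolysis list held Ldhb (8718 ± 323), Eno1 (8087 ± 741), Aldoa (6946 ± 415) and Pgk1 (6669 ± 358) and the glucose carrier gene Slc2a3 (7.86 ± 7.41). In the liver list, Fga gave 68.3 ± 6.46, Apob 47.7 ± 24.8, Arg1 44.5 ± 15.9, Fgb 31.3 ± 1.57, Alb 18.2 ± 4.54 and Otc 1.59 ± 0.572.

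Regulators were examined in the lists of transcription factors and of mineral hormone signalling. Transcription factors of the proximal tubule had a median percentile of 74.4 (adjusted permutation p = 0.036), and 18 of 18 lay above the array median on all 3 arrays (Fisher's exact test, adjusted p = 0.00085). Hnf4a, a master regulator of this epithelium, gave 5488 ± 364, Maf 5435 ± 572, the bile acid receptor gene Nr1h4 1601 ± 97.2, Esrrg 854 ± 47.8 and Ppara 46.5 ± 16.9. The call of the level test ended when random lists were matched on the number of probe sets (adjusted permutation p = 0.054) and when the lowest 20% of genes were left out (0.13). In the list of vitamin D, parathyroid hormone and FGF23 signalling (median percentile 63.9, adjusted permutation p = 0.45), the parathyroid hormone receptor gene Pth1r gave 3357 ± 394, Fgfr1 270 ± 22.9, Fgfr4 269 ± 40.5, Fgfr3 247 ± 14.8 and Cyp27b1, the vitamin D 1-alpha-hydroxylase gene, 41.2 ± 4.35. All 9 measured members lay above the array median on all 3 arrays (Fisher's exact test, adjusted p = 0.026).

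**Figure D2:**
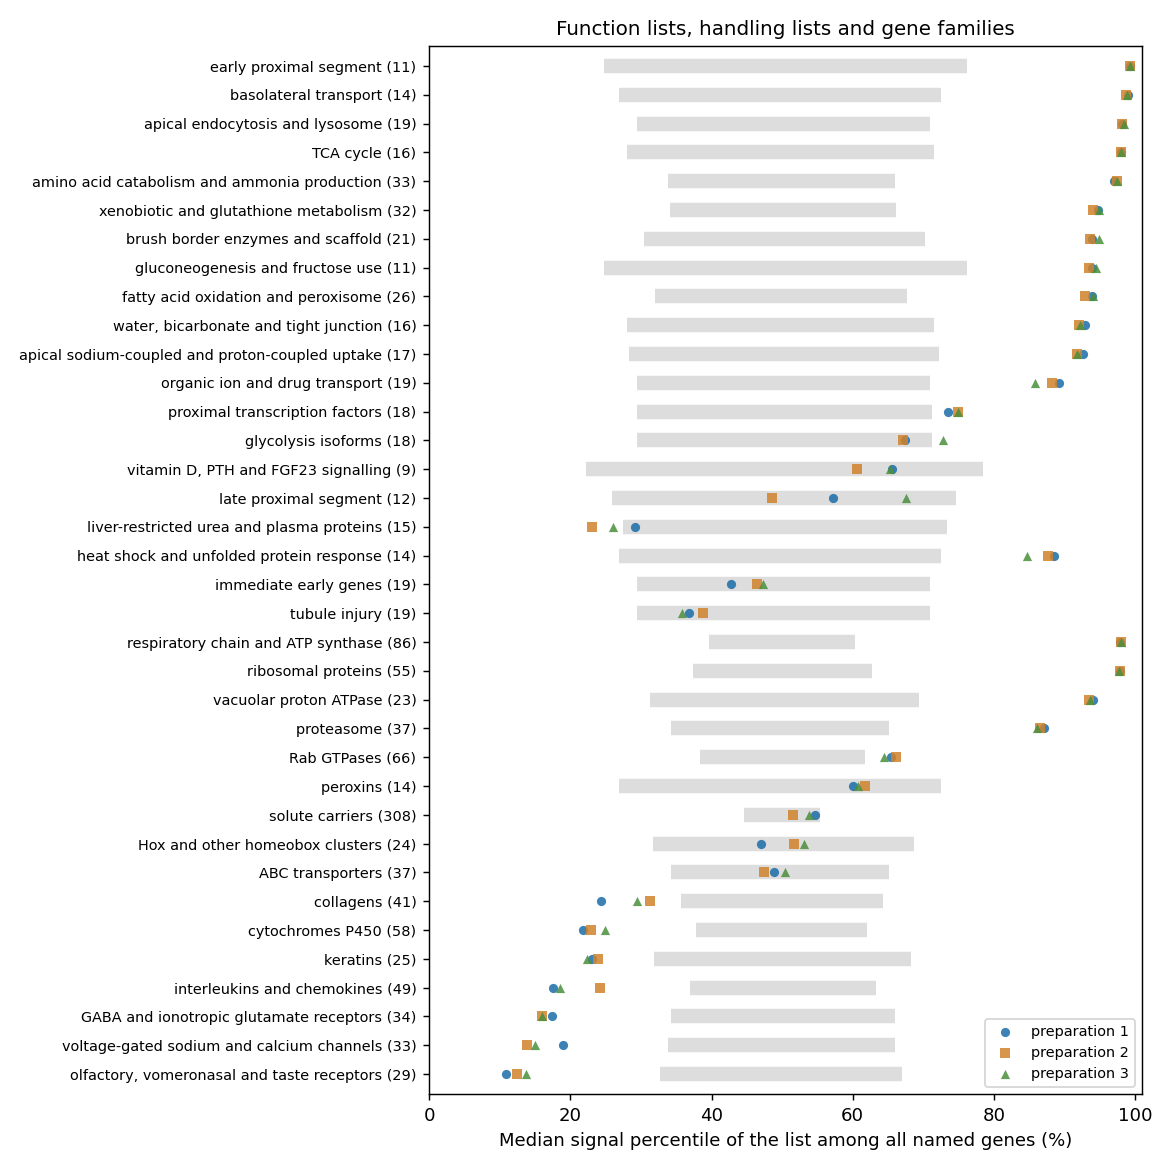
Median signal percentile among all named genes (x axis, %) on each of the 3 preparations for function lists, handling lists and gene families (y axis, number of measured genes in parentheses). Grey bands hold 95% of random lists of the same size; early segment (99.3), basolateral transport (98.9) and respiratory chain (97.9) lie right of their bands, and olfactory, vomeronasal and taste receptors (12.3) lie left of theirs.

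Of 16 gene families, 5 lay above and 7 below random lists. Above were the respiratory chain and ATP synthase (median percentile 97.9; Atp5f1b 9619 ± 472), ribosomal proteins (97.8; Rps29 9966 ± 720), the vacuolar proton ATPase (93.7; Atp6v0c 5211 ± 543), the proteasome (86.5; Psmb4 2906 ± 220) and Rab GTPases (65.3; Rab7a 2840 ± 168). Below were olfactory, vomeronasal and taste receptors (12.3), voltage-gated sodium and calcium channels (15.9), GABA and ionotropic glutamate receptors (16.4), interleukins and chemokines (20.1), keratins (23.2), cytochromes P450 (23.2) and collagens (28.4). Their adjusted permutation p-values ran from 0.00045 to 0.016, the largest for Rab GTPases, whose call ended when a gene's probe sets were averaged (adjusted permutation p = 0.13). Members of families below random lists still included genes far above the array median, such as Cyp2c23 and Cyp2e1 (4123 ± 418) among the cytochromes P450 and Krt8 (1422 ± 211) among the keratins. Solute carriers as a whole (53.3), peroxins (60.8), Hox and other homeobox genes (50.7) and ABC transporters (48.9) were not called. The symbol patterns also took in a few genes that are not family members, such as the kinase gene Rps6ka2 among the ribosomal proteins.

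Genes of handling and injury responses were examined because isolation involved enzyme digestion. No undigested tissue was measured, so the level of a list cannot show whether isolation changed it. Heat shock and unfolded protein response genes had a median percentile of 86.9 (adjusted permutation p = 0.0016). They included the mitochondrial chaperone genes Hspd1 (6390 ± 374) and Hspe1 (6287 ± 617), the endoplasmic reticulum chaperone gene Hspa5 (4058 ± 1410), Dnaja1 (2588 ± 640) and Hspb8 (18.0 ± 3.55). Immediate early genes (45.5, adjusted permutation p = 0.74) and tubule injury genes (37.2, adjusted permutation p = 0.32) were not called. Among the first, Jund gave 1677 ± 268, Jun 770 ± 154, Zfp36 532 ± 97.46, Dusp1 266 ± 17.9, Fos 234 ± 48.1 and Gadd45b 7.95 ± 4.24. Among the second, Krt8 stood beside Spp1 at 728 ± 277, Anxa2 at 192 ± 8.86, Clu at 126 ± 25.9, the kidney injury marker Havcr1 at 19.0 ± 2.51 and Plaur at 2.38 ± 0.950. Without the lowest 20% of genes, the injury list lay below random lists, at a median percentile of 22.3 (adjusted permutation p = 0.014).

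Over all genes, 8674 of 14217 (61.0%) lay above the array median on all 3 arrays, and by Fisher's exact test 17 lists held more and 11 held fewer such members than the other genes. The 15 genes named for their mean signal, which depends on probe affinity as well as on abundance, are given in alphabetical order. They were Akr1a1, Ass1, Atp5f1b, COX1 (12069 ± 539) and COX2 (12969 ± 1451) of the mitochondrial genome, Ctsa (10273 ± 537), Ctsl, Gatm, Gpx3, Hao2, Hpd, Miox, Rps29, the selenium carrier gene Selenop (11492 ± 687) and Slc34a1.

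The 3 preparations were then compared with each other. The ratio of the 3' to the 5' control probe set was 3.85, 3.28 and 3.66 for beta-actin on arrays 1, 2 and 3. For GAPDH it was 1.52, 1.52 and 1.40. Whether RNA quality contributed to differences between the preparations was not tested. Across 31042 probe sets, Pearson's r between arrays was 0.981, 0.980 and 0.979 and Spearman's rho 0.947, 0.944 and 0.945 for arrays 1 and 2, 1 and 3, and 2 and 3. These are correlations across genes, which are not independent replicates. From 675 to 747 probe sets (2.17% to 2.41%) differed by 2-fold or more in a pair. The median SD over arrays was 0.15 on the log2 scale for genes above the median level and 0.24 for the others.

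Of 7108 genes above the median level, 99 (1.39%) ranged over the arrays by 2-fold or more. The 10 largest ranges were those of RT1-Bb, Mx2, Bcl6, Ccn2, Slc7a13, Fam111a, Pxmp4, Slc38a3, Cish and RT1-T24-4. RT1-Bb, an MHC class II chain, gave 1169, 20.7 and 2230 on arrays 1, 2 and 3 (range 6.005 log2 units), Mx2, an interferon-induced GTPase, gave 1117, 14.99 and 809 (5.20), and Bcl6, a transcriptional repressor, gave 675, 31.1 and 634 (3.88). Ccn2, a connective tissue growth factor, gave 2298, 263 and 517 (3.06). The late-segment transporter gene Slc7a13 gave 209, 73.6 and 638 (2.94). Slc38a3, the glutamine carrier gene, gave 204, 37.3 and 266 (2.47). Cish, an inhibitor of cytokine signalling, gave 67.2, 410 and 58.8 (2.44). With a gene's probe sets averaged, the range was 1.22 for RT1-Bb, whose other probe set gave 36.7, 344 and 13.2, and 4.48 for Mx2. Without array 2 the ranges were 0.99 for RT1-Bb, 0.39 for Mx2, 0.02 for Bcl6, 1.60 for Slc7a13, 0.42 for Slc38a3, 0.09 for Cish and 0.64 for RT1-T24-4. Without array 1 those of Ccn2, Fam111a and Pxmp4 were 1.004, 0.52 and 0.34, and without array 3 that of Slc7a13 was 1.33. Of the 99 genes, 28 lay farthest from their mean by being low on array 2, 19 by being high on array 1 and 19 by being high on array 3. With 1 array per preparation these differences could not be tested, and the count was 36 among genes above the 75th percentile of mean level and 47 to 51 when 1 array was left out.

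**Figure D3:**
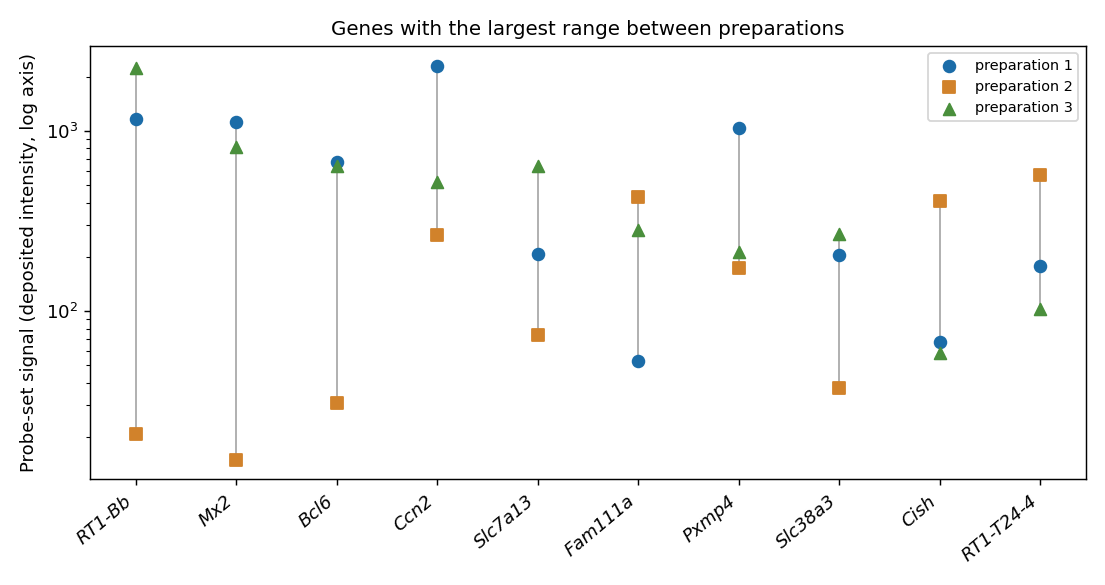
Signal on each of the 3 preparations (y axis, deposited intensity, log scale) for the 10 genes with the largest range among genes above the median level (x axis). Each marker is 1 array and the grey line spans the range; RT1-Bb, Mx2 and Bcl6 are lowest on preparation 2, at 20.7, 14.99 and 31.1, and Cish is highest there, at 410.

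Marker lists shifted between preparations by smaller amounts. On array 3, lists of other cells lay high: intercalated cells by 0.29 log2 units, endothelium by 0.25, fibroblasts by 0.25, thin limb by 0.24, macrophages by 0.23 and principal cells by 0.19, all above the central 95% of level-matched random lists. Plvap gave 185, 286 and 396 and Pecam1 42.8, 74.2 and 137 on arrays 1, 2 and 3. Col3a1 gave 43.2, 68.6 and 102, Mgp 172, 223 and 361, and Atp6v1g3 63.3, 73.0 and 106. In the principal cell list, Aqp2 gave 4.25, 4.80 and 32.9 and Aqp4 1.10, 0.75 and 10.2. In the thin limb list, Bst1 gave 1.64, 4.52 and 21.1 and Calca 31.9, 4.15 and 33.4. Aqp2, Aqp4, Bst1 and Calca lay below the median of every array. The proximal tubule list deviated by 0.05 on array 3, within the range of random lists. Brush border (0.12), fatty acid oxidation (0.09) and amino acid catabolism genes (0.09) lay high there. Immediate early genes were also high on array 3 (0.17; Fos 199, 214 and 289), and heat shock genes were low (-0.13; Hspa5 5611, 3703 and 2859, Ddit3 284, 195 and 147). Without array 1, the array 3 shifts of intercalated cells (0.14), fibroblasts (0.06), thin limb (0.21), immediate early (0.10), amino acid catabolism (0.09) and ribosomal protein genes (0.05) were not called. Without array 2 those of macrophages (0.08), thin limb (0.10) and fatty acid oxidation genes (0.01) were not. Endothelial, principal cell, brush border and heat shock shifts kept their call in both. But the endothelial shift was not called among values above the median (0.14), nor the principal cell shift with averaged probe sets (0.15), nor that of amino acid catabolism with suffix-free probe sets (0.07). The intercalated, fibroblast, principal cell and thin limb lists had fewer than 4 members above the median. Their shifts could therefore not be checked among such values. The thin limb shift also kept its call in only 2 of 6 other settings.

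On array 1, endothelial (-0.26), podocyte (-0.27), fibroblast (-0.23), intercalated cell (-0.22), immediate early (-0.20) and Hox genes (-0.16) lay low and organic ion transporters high (0.14). On array 2, red blood cell (-0.26), distal convoluted tubule (-0.22), vitamin D and parathyroid hormone (-0.21), principal cell (-0.19), macrophage (-0.17), organic ion transport (-0.16) and liver-restricted genes (-0.16) lay low, among them Calb1 at 292, 214 and 390 and Klk1 at 112, 70.9 and 116. Hox genes (0.09) and interleukin and chemokine genes (0.07) lay high on array 2. The interleukin and chemokine shift was not called with quantile normalization (0.06). It was negative among values above the median (-0.18) and without array 1 (-0.00078). Ribosomal proteins on array 3 (-0.0056) and Rab GTPases (0.0014) and transcription factors (-0.011) on array 1 lay below their random lists, but the sign of these deviations turned with a pseudocount of 1, with quantile normalization or a pseudocount of 1, and without centring, in that order. In all, 30 of 150 pairs of list and array lay outside the central 95% of random lists, against 7.5 expected if the lists were random. The shifts of the vitamin D, principal cell, red blood cell and liver-restricted lists on array 2 kept their call in 3 of 7, 3 of 6, 3 of 6 and 3 of 6 other settings. When 1 other array was left out, so that a shift was measured against the remaining array alone, the podocyte shift on array 1 was -0.17 or -0.07 and was not called, as with averaged (-0.17) or suffix-free probe sets (-0.22). Without array 3, shifts not called were those of intercalated cells (-0.03) and Rab GTPases (0.05) on array 1 and of the distal convoluted tubule (-0.08), vitamin D (-0.10) and principal cell lists (-0.03) on array 2. Without array 1, those of red blood cell (-0.23), organic ion (-0.07), liver-restricted (-0.08) and Hox genes (0.02) on array 2 were not called. Without array 2, the transcription factor shift on array 1 (-0.01) was not called. Other calls lost were those of organic ion transport on array 2 with quantile normalization (-0.04) and above the median (-0.14), and on array 1 with a pseudocount of 64 (0.10). The macrophage shift on array 2 (-0.14) and that of Rab GTPases on array 1 (0.0072) were not called with averaged probe sets, nor the latter above the median (0.03).

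**Figure D4:**
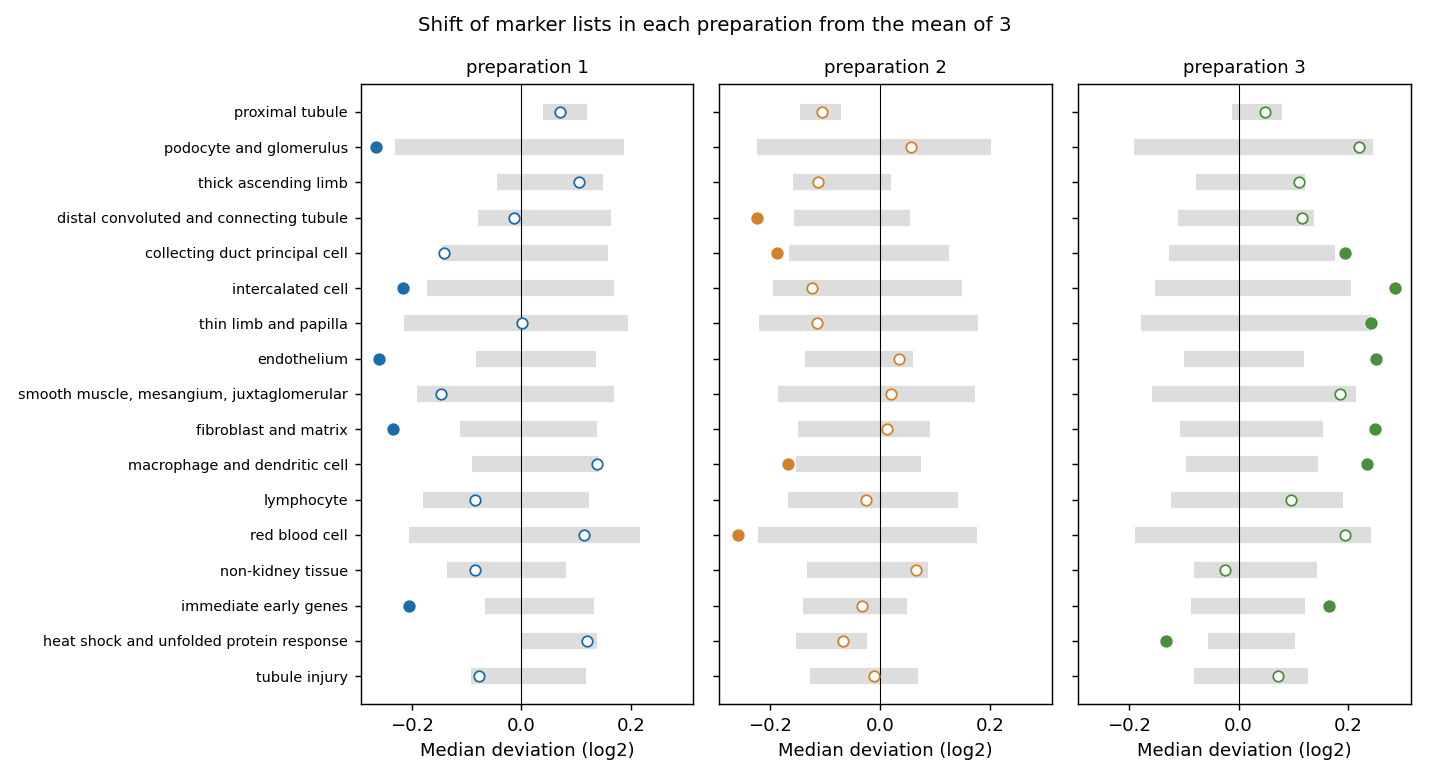
Median deviation of each marker and handling list from the mean of 3 preparations (x axis, log2 units) on preparations 1, 2 and 3. Grey bands hold 95% of level-matched random lists and filled points lie outside them; on preparation 3 the endothelium (0.25), fibroblast (0.25) and intercalated cell (0.29) lists lie right of their bands, and heat shock genes (-0.13) lie left.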

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

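The alternatives here were planned. No paired analysis was possible because the 3 arrays form 1 group. The calls of the proximal tubule, lymphocyte and non-kidney lists held under every alternative of the level test, and the 13 differences between the proximal tubule list and the other cell type lists kept their sign and their call in all 65 recomputations. Of the recomputed list levels, 324 kept their side and call, 10 gained a call, 3 lost it and 12, of lists called in neither case, crossed the middle. With 3 arrays and no detection calls, signals near background set the limit: genes below the median level had a median SD of 0.24 log2 units between arrays against 0.15 above it, and calls of dim lists moved with the filter on low values.

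Values below are median percentiles, with adjusted permutation p-values in parentheses, and the cause of a changed call was not tested. Averaging a gene's probe sets brought the thin limb list (16.7, permutation p = 0.039) and solute carriers (56.0, permutation p = 0.046) past the threshold, ended the call of Rab GTPases (60.3, permutation p = 0.13) and put the uncalled ABC transporters at 54.8. With only probe sets without a shared-transcript suffix, the liver-restricted list passed (23.8, permutation p = 0.038), and 3 uncalled lists crossed the middle: endothelium 45.6, vitamin D and parathyroid hormone 44.5 and ABC transporters 50.6. With random lists matched on the number of probe sets, the thin limb list passed (21.98, permutation p = 0.047), proximal transcription factors did not (74.4, permutation p = 0.054), and ABC transporters at 48.9 lay on the other side of their random lists. Without the lowest 20% of genes, podocytes (15.03, permutation p = 0.026), smooth muscle (14.5, permutation p = 0.010), macrophages (22.9, permutation p = 0.026), liver-restricted genes (15.7, permutation p = 0.0076) and tubule injury genes (22.3, permutation p = 0.014) passed. This made 14 lists below in place of 9, and transcription factors did not pass (68.0, permutation p = 0.13). There, uncalled lists that crossed the middle were thick ascending limb 49.3, distal convoluted tubule 49.4, endothelium 41.4, ABC transporters 52.5 and Hox genes 43.2. Leaving out 1 array gave 48.4 to 51.8 for endothelium and 49.4 to 52.4 for Hox genes. Liver-restricted genes gave 24.5 to 27.6 and passed without array 1 (permutation p = 0.042).

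With the 75th percentile as the line, 5172 genes lay above it on all 3 arrays, fewer by construction. The lowest Pearson r between arrays was 0.945 with a pseudocount of 1 and 0.988 with 64, and 0.979 to 0.981 when 1 array was left out. The median SD of a probe set was 0.186 with quantile normalization, 0.162 for values above the median, 0.305 and 0.108 with pseudocounts of 1 and 64, and 0.149 to 0.154 when 1 array was left out. The count of genes with a 2-fold range, 99, became 60 with a pseudocount of 64, 634 with no filter on low values, 36 above the 75th percentile of mean level and 47 to 51 when 1 array was left out, where a range over 2 arrays is smaller by construction. The range of RT1-Bb fell from 6.005 to 1.22 log2 units with averaged probe sets, as its 2 probe sets ran in opposite directions. Of the recomputed shifts of called lists, 208 kept their call, 52 lost it, and none lay outside chance on the other side of its random lists.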

Other observations

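All patterns in this part were noticed in the data before a test was chosen; the tests of bright interferon-response genes, RT1 alleles, antigen-presenting cells, scaling, dim signals and the thick ascending limb, and every restriction to genes with a mean signal above the array medians (called bright here), were chosen after results had been seen, and the others before. Genes named here outside the rule for naming were chosen after their values were seen.

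Genes of the early proximal segment had a median percentile of 99.3 (11 genes), and genes of the late segment one of 57.8 (12 genes), which was 57.2, 48.6 and 67.6 on arrays 1, 2 and 3. Most of the early list also stands in the proximal tubule list, and of the late list only Slc7a13. The contrast may thus partly reflect how the lists were filled. The late list held Slc3a1 at 8801 ± 781, Acsm3 at 3282 ± 568, Slc5a1 at 39.6 ± 4.25 and Slco1a6 at 48.7 ± 37.4. Of the 9780 probe sets with no gene named here, 26.6% lay above the array median on all 3 arrays, against 54.5% of probe sets with 1 gene. Above the 95th percentile of the array on all 3 arrays lay 110 of them (1.12%), against 5.82% of probe sets with 1 gene.

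Markers of other cell types were higher in preparation 3, where all 12 lists of other kidney and blood cells deviated upward by 0.10 to 0.29 log2 units, 6 with an interval above 0. In preparation 1, 8 of the 12 lay below 0, 1 with an interval below 0. The deviations of a gene sum to 0 over arrays 1, 2 and 3, so the values of preparation 1 are not separate support. A rise of all dim signals is argued against by genes of the same level, which the 124 genes of the 12 lists exceeded by a median of 0.17 (95% interval 0.12 to 0.22). The 62 with a mean signal above the array medians exceeded them by 0.15 (0.060 to 0.23) and the 62 others by 0.19 (0.12 to 0.23). The shifts of these lists had already been set against random lists of the same level, so this excess is not independent evidence. A first test on the non-kidney list (-0.024) was replaced, as nearly all its genes lay near the floor. A larger share of vessel, stromal and collecting duct cells may be the source, since 54 further markers of these cells and of macrophages deviated by 0.22 (0.11 to 0.27), 44 of them upward, and the 22 bright ones by 0.24 (0.14 to 0.31), 21 of them upward, with 32 near the floor left out. By type, further endothelial markers deviated on array 3 by 0.29, stromal by 0.24 and collecting duct by 0.23, all above the central 95% of random lists. Macrophage markers deviated by 0.034, within it. On array 1 the endothelial (-0.33) and stromal markers (-0.29) lay at least as far below 0, and macrophage markers lay above random lists (0.13). Collecting duct markers lay below random lists on array 2 (-0.24). A smaller share of vessel and stromal cells in preparation 1 therefore cannot be told apart from a larger one in preparation 3. Sparc gave 371, 513 and 578 and Ptprb 179, 203 and 248 on arrays 1, 2 and 3. But Serpinf1 (5580, 4830 and 5408), Krt7 (1984, 1469 and 1702) and Tmprss2 (677, 378 and 649) gave lower uncentred signals on array 3 than on array 1. A smaller share of proximal cells, raising every other cell type alike, stays open. The interval of the thick ascending limb list on array 3 (0.11, -0.033 to 0.25) includes 0.21, the median of the 12 lists. An earlier test on Umod (0.11), Egf (-0.033) and Slc12a1 (-0.17) had counted against this explanation. That test was replaced after its result was seen because a few bright members do not stand for the list. Cldn10 deviated by -0.067 but decides nothing, as it also stands in the list of water, bicarbonate and tight junction genes.

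Of the 99 genes with a 2-fold range between arrays, 27 had another probe set above the median signal. For these 27, noise or a sequence variant confined to 1 probe set is argued against as the general cause. Their other probe sets followed the first by a median factor of 0.68 (0.49 to 0.89), 18 by more than 0.5. The second Mx2 probe set gave 359, 11.8 and 200. The remaining genes could not be tested in this way, among them Bcl6, Ccn2, Slc7a13, Fam111a, Slc38a3 and RT1-T24-4, which had 1 probe set each. Weaker interferon signalling in preparation 2 is argued against as the whole cause for Mx2, which deviated there by -3.33, by 6 other bright interferon-response genes at a median of -0.024 (-0.27 to 0.077), 4 of them with mean signals of only 39.3 to 65.8, and by their -0.27 and 0.23 on arrays 1 and 3, lowest where Mx2 gave 1117; the test set in advance had used all 17 (-0.13, -0.037 and 0.17 on arrays 1, 2 and 3, 12 of them below 0 on array 2, with Mx1 at 24.8, 12.5 and 40.1), but 11 lay near the floor and decide nothing. For RT1-Bb, the other probe set moved the opposite way (36.7, 344 and 13.2 on arrays 1, 2 and 3; factor -0.58), consistent with MHC alleles that differ between animals and are read by different probe sets. This is a hypothesis from 2 genes, and the second does not repeat the first: of the 3 other RT1-Ba probe sets, 1 gave 997, 739 and 29.1 (factor -1.61), low on array 3, 1 followed by 0.38, and 1 below the median signal (38.4, 22.2 and 13.1) was left out. Fewer antigen-presenting cells in preparation 2 are argued against as the whole cause for RT1-Bb. It differed there from the mean of the other arrays by -5.51, where Cd74, RT1-Da and Lyz2 differed by -1.12 at the lowest. This explanation stays open for RT1-Ba (-1.72), since these 3 genes had a median of -0.74 (from -1.12 to -0.25), 2 of them class II pathway genes themselves. As deviations from the mean of all 3 arrays, which are smaller by construction, the macrophage list gave -0.17, below random lists. Its 8 bright members gave -0.35 (-0.75 to -0.14), also below them. The 14 further macrophage markers gave -0.092, within random lists.

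Of the genes with a 2-fold range, 5 known as hormone or clock targets were singled out after their values were seen. No enrichment of such genes was tested. Bcl6 was low and Cish high in preparation 2. Per1 (242, 76.0 and 70.8 on arrays 1, 2 and 3), Per2 (719, 333 and 220) and Ddit4 (469, 118 and 243) were high in preparation 1. The other Per2 probe set gave 88.6, 6.39 and 67.2, lowest on array 2, with a smaller gap between arrays 1 and 3. Bcl6, Per1 and Ddit4 had 1 probe set each, so noise or a sequence variant confined to it could not be tested for them. The test of a scaling difference of array 2 decides nothing from Bcl6 (-3.87) and Cish (2.39), which were singled out for running in opposite directions there. The median of genes above the median level differed there by only -0.073 without centring, less than either gene. Recent growth hormone and STAT5 signalling in preparation 2 stays open: Socs2, another target, differed by -0.30, and a value this low had been set in advance to count against it, but Socs2 gave 13.9, 4.05 and 3.32, below the median of every array, where it decides nothing, and Igf1, a further target (96.6, 37.1 and 53.1), differed by -0.77, against this explanation but as a single gene. A different clock phase in preparation 1 could underlie the Per genes. On array 1, clock genes peaking with Per (0.20) and opposite to Per (-0.41) lay outside random lists. Of the first list, 7 of 8 genes lay above 0 there, but Nr1d1 did not (106, 155 and 172 on arrays 1, 2 and 3). Of the second list, 1 of 5 lay above 0, Cry1 (76.2, 32.5 and 47.4). The difference of the 2 list values, 0.60, passed the 0.5 set in advance. The explanation stays open because the interval (-0.27 to 1.02) includes 0 and bright genes gave 0.42. On array 3 the lists lay outside the other way (-0.22 and 0.39). That is not separate support, since the deviations of a gene sum to 0 over arrays 1, 2 and 3. Stronger glucocorticoid signalling also stays open, with a list deviation of 0.15 (-0.010 to 0.38) on array 1, above random lists but under the 0.3 set in advance. The -0.11 of that list on array 3, below random lists, is for the same reason not separate support. On array 1, 9 of 12 members lay above 0, and the 11 bright ones gave 0.18 (0.033 to 0.40). Sgk1 gave 4879, 2630 and 2964 and Tsc22d3 863, 503 and 491. But Klf9 (2304, 2380 and 2002), Mt2A (4284, 4415 and 3677) and Dusp1 (250, 263 and 285) were not high on array 1.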
